A study of Arabidopsis thaliana with 18 samples.

How the data were processed

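RNA was measured in 18 libraries of leaf 5 of Arabidopsis thaliana, with 3 libraries for each of 6 groups: margin and center of Col-0, of tcp2tcp4 and of tcp2tcp3tcp4tcp10. Per the labels' protocols, plants grew at 23 °C with 16 h of light and 8 h of dark, 5 days on plates and then on soil. Leaf 5 was taken at emergence of leaf 7, at Zeitgeber time 6, and cut on a cold plate into margin and center, with 15 to 20 plants per library. The lines were placed in the greenhouse 2 days apart, the quadruple mutant first and Col-0 last, so genotype and plant age cannot be told apart. RNA was extracted with TRIzol, treated with DNase and made into libraries with an Illumina TruSeq RNA kit. The submitters' processing notes name TopHat2 2.0.13, HTSeq 0.7.2, edgeR 3.8.6 and the TAIR10 genome. What each program did, its options, the strand of counting and the annotation release are not given in the sources used here.

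The deposited table held raw integer read counts per locus, as the authors made them, for 33602 loci in 18 columns, all used, and 5 summary rows of reads not counted in genes. The summary rows stayed out of library sizes and tests: reads without a feature were 0.497% to 1.15% of the total, ambiguous reads 1.38% to 1.57% and reads aligned to several places 3.71% to 16.0%. In all 32835 loci (97.7%) matched the reference gene table of TAIR10.1, which was used for names alone, so no coordinates are given. 9788 loci had no read. Because the strand of counting is not stated, reads of loci that overlap another gene cannot be assigned with certainty: among the genes named this concerns AIR3, AK3, AS1, ASN1, BCAT4, CESA8, CKX5, CYCA2;3, CYP708A1, CYP71A13, FKF1, FRO3, G6PD3, GC1, GL2, GRF1, GRF3, GRF9, KNOLLE, LHCB4.2, LNK1, MP, PP2-A1, PSAE1, REV, RGF6, TCP3, WRKY29 and XCP1.

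Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3), with TMM scaling, filterByExpr by group, which left 17763 loci, and a model with 1 mean per group over all 18 libraries. The p values, 2-sided, were adjusted by Benjamini-Hochberg over all loci tested, and genes with an adjusted p under 0.05 were called. The number of calls changed at least 2-fold is given beside each count. The SE of a log2 fold change was taken from the F statistic, and the median SE was 0.114 to 0.123 between groups and 0.167 to 0.174 for interactions. Comparisons were margin against center within a genotype, genotypes within a compartment, and the interaction, which is the margin minus center difference of 1 genotype minus that of another. CPM values were scaled by TMM, and principal components used log2 CPM with a prior count of 2. Where a group had 1 to 3 reads of a gene in all, the ratio is given with its counting interval, and where it had 0, a bound from a floor of 3 counts. Such intervals cover counting error only.

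The 31 gene lists were fixed before the data were examined, as were the comparisons, tests, alternatives and the rule for named genes. They held 369 loci, of which 317 passed the filter, and covered the miR319-regulated and other CIN-class TCP genes, known targets of these factors, boundary and KNOX genes, GRF and GIF genes, the cell cycle, photosynthesis, hormones, flavonoids and glucosinolates, vascular and epidermal cell types, leaf polarity and outgrowth, the meristem, phase change, the clock, handling stress and senescence. The 30 lists with at least 3 loci tested were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with p values adjusted over the 30 lists of a comparison, and again with an estimated correlation. Each list is also given the number of members called when p values were adjusted over its members alone.

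The rule for named genes had 3 parts. TCP2, TCP3, TCP4 and TCP10 are named in every group. In margin against center of Col-0 and in the quadruple mutant against Col-0, the 8 highest and 8 lowest log2 fold changes are named among called genes with a symbol, at least 5 CPM in the higher group and no overlap between the libraries of the 2 groups. Other comparisons take 4 and 4, and interactions leave out the last condition. From each list come up to 4 members, the 2 lowest adjusted p in each direction among those called. Genes and lists named outside this rule are marked as chosen after their values were seen.

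Whether libraries of the same number came from the same leaves is not stated, so it was tested on the 5000 most variable genes after removing group means. Margin and center libraries of 1 genotype with the same number correlated at 0.196 to 0.384 (9 pairs), all 18 libraries correlated best with the partner of their own number, and pairs with other numbers reached −0.238 to 0.0383. The leaf pool, 9 pools in all, was therefore also used as a block, and blocked counts stand beside the results for compartments and interactions. Without a block the biological coefficient of variation was 7.68%, and with the leaf pool as a block 3.48%. Across genotypes, pairs with the same number correlated at −0.233 to 0.180.

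The pipeline was tested on simulated data with 200 changed genes. For margin against center in Col-0 it recovered 68.7% of changes of 1.5-fold, 94.0% of 2-fold and 100% of 4-fold, with 4.37% false among 183 calls. For the quadruple mutant against Col-0 in the margin these were 68.7%, 82.1% and 98.5%, with 7.26% false among 179. For the interaction of the quadruple mutant they were 37.3%, 62.7% and 95.5%, with 3.70% false among 135. With deviations shared within a leaf pool, the block gave 6.91% false calls for margin against center and 9.70% for the interaction, and no block 0.592% and 0%. Correlation between genes was not simulated. A shifted mitotic list was called in 10 of 10 simulations, others in 2 of 287 tests.

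Alternatives fixed beforehand were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no low count filter, a filter of 1 CPM in 9 libraries, the block, only the libraries compared in the model, each library left out, the estimated correlation for lists and a 2-fold selection for slopes. Added after the data were seen were a fit without the 2 libraries richest in reads aligned to several places, thinning of all libraries to 5932877 reads, and scaling without the 100 most abundant genes and the light harvesting list. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.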

Results

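The data held 18 RNA-seq libraries of Arabidopsis leaf tissue in 6 groups of 3 libraries. Leaf 5 of wild-type Col-0, of the double mutant tcp2tcp4 and of the quadruple mutant tcp2tcp3tcp4tcp10 was cut into a margin piece and a center piece. TCP2, TCP3, TCP4, TCP10 and TCP24 encode transcription factors whose transcripts are targets of the microRNA miR319 and which are known to end cell proliferation in leaves. Reads counted in genes ranged from 5.93 M (double mutant center 1) to 12 M (quadruple mutant center 2), and 19850 to 20756 loci had a read. The mean depth of the Col-0 margin was 7.73 ± 1.32 M reads (SD, n = 3) and of the Col-0 center 8.61 ± 0.108 M. In the double mutant it was 8.94 ± 2.67 M for the margin and 7.26 ± 2.28 M for the center, and in the quadruple mutant 9.69 ± 1.25 M and 9.29 ± 2.58 M. Fold changes below are log2 values ± SE from 3 libraries per group, and levels are CPM (counts scaled to library size) ± SD of 3 libraries.

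The first principal component of the log2 CPM values held 36.3% of the variance and ran from the Col-0 margin to the quadruple mutant libraries. The second held 22.3% and ran from the margin to the center libraries. In the double mutant margin library 3, 16.0% of the reads aligned to several places and 0.209% of the gene reads were chloroplast reads. In the Col-0 margin library 1 these shares were 8.60% and 0.104%, and in the other 16 libraries 3.71% to 4.97% of reads aligned to several places. The 10 most abundant genes took 13.6% of the gene reads in the Col-0 margin and 8.93% in the quadruple mutant margin (means of 3 libraries).

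**Figure D1:**
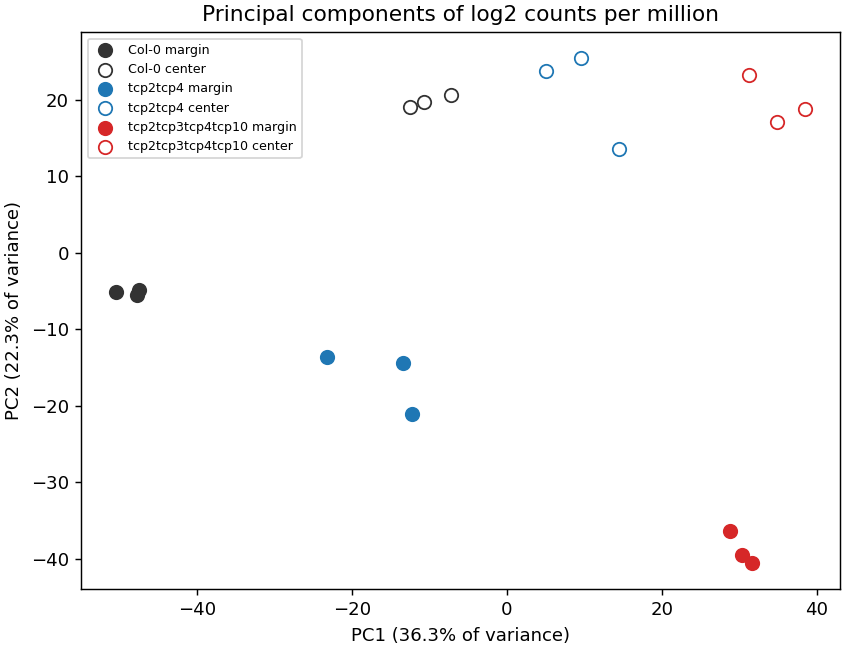
Scores of the 18 libraries on the first 2 principal components of log2 CPM, by genotype (colour) and leaf compartment (filled, margin; open, center).

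The transcripts of the mutated genes were measured first, as a check of the genotype of each library. TCP2 was at 63.4 ± 2.54 CPM in the Col-0 margin and 65.2 ± 1.4 in the center, and at 17% and 12.7% of those levels in the double mutant and 13.9% and 11.3% in the quadruple mutant. TCP4, at 110 ± 8.57 CPM in the Col-0 margin and 79.2 ± 5.42 in the center, stood at 18.7% and 19.0% of Col-0 in the double mutant and at 21.5% and 24.8% in the quadruple mutant. TCP10 was at 80.0 ± 1.49 and 61.5 ± 4.24 CPM in Col-0. Its level was 115% and 103% of Col-0 in the double mutant, where it did not pass the test (adjusted p = 0.191 in the margin), and 11.1% and 8.11% in the quadruple mutant. TCP3 had few reads, 2.81 ± 0.949 CPM in the Col-0 margin and 1.98 ± 0.804 in the center, with 15.3% of the margin level left in the quadruple mutant. TCP24, mutated in neither line, was at 58.5 ± 4.06 CPM in the Col-0 margin and 66.3 ± 5.26 in the quadruple mutant margin. That difference of 0.18 ± 0.072, adjusted p = 0.0469 passed the test, but not with DESeq2, without a low count filter or without the Col-0 margin library 1 or 2, among other alternatives.

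**Figure D2:**
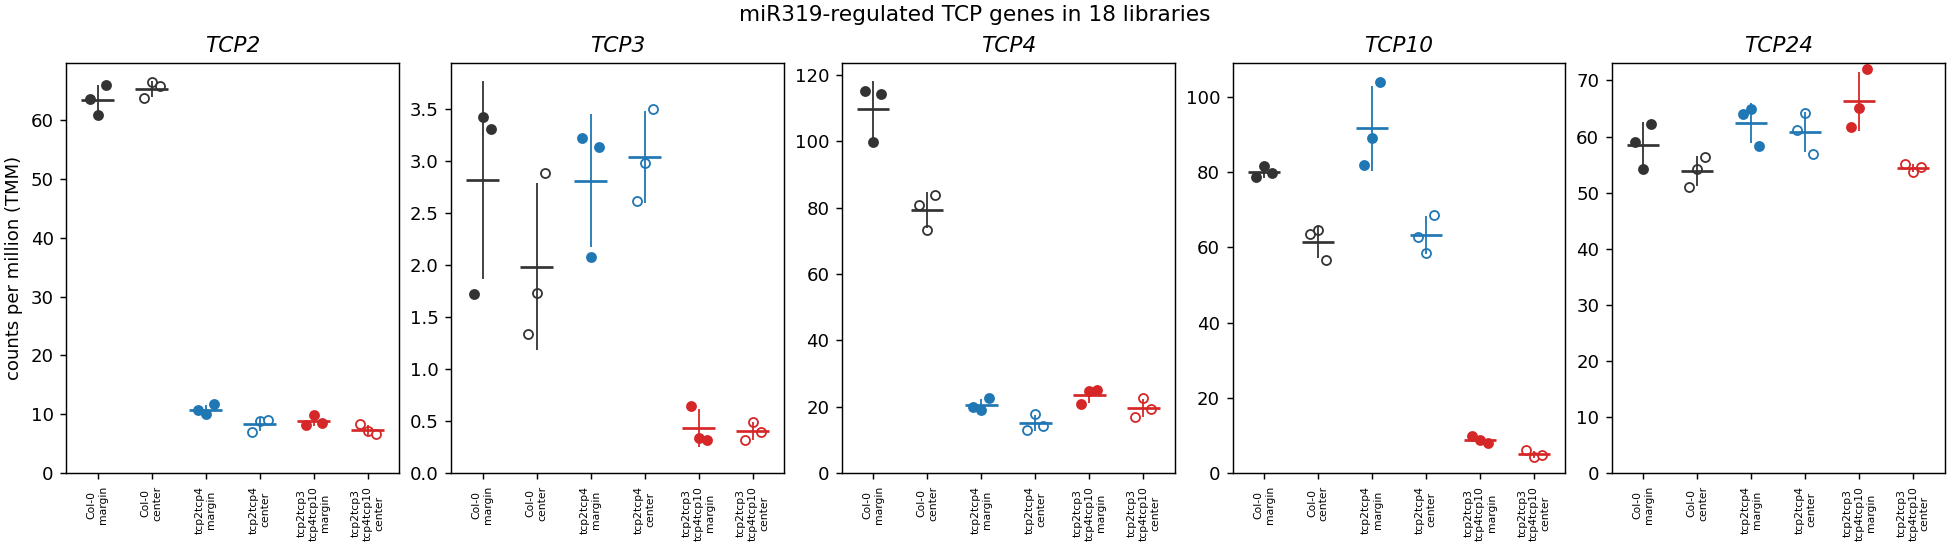
CPM of the 5 miR319-regulated TCP genes in each of the 18 libraries, with the mean and SD of 3 libraries per group.

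The comparison of margin with center in Col-0 asked how the wild-type leaf differs along its width. The mitotic list was lower in the margin than in the center and the light harvesting, phloem and guard cell lists were higher, but none of the 4 passed with an estimated correlation. 24 of 31 mitotic genes passed the test, all lower in the margin. In all, 2030 genes (11.4% of 17763) differed at an adjusted p under 0.05, 941 higher and 1089 lower in the margin. Of these, 171 and 276 differed at least 2-fold, and with the leaf pool as a block 3836 genes were called. Among the 16 genes with the largest changes, those higher in the margin were led by the phosphate transporter gene PHT1;4, at 10.4 ± 1.15 CPM against 0.492 ± 0.449 in the center (4.37 ± 0.42, adjusted p = 4.66e-07). The defense regulator gene WRKY29 (4.19 ± 0.34, adjusted p = 4.94e-08), BHLH100 of the iron deficiency response (3.48 ± 0.58, adjusted p = 3.9e-04) and the phloem lectin gene PP2-A5 (2.74 ± 0.42, adjusted p = 1.8e-04) followed. DES1, for a cysteine desulfhydrase, was higher by 2.46 ± 0.20, adjusted p = 4.47e-08, the protease gene AIR3 by 2.35 ± 0.12, adjusted p = 5.39e-11 and the glutamine synthetase gene GLN1;4 by 2.04 ± 0.23, adjusted p = 5.03e-06. TAA1, which encodes the first enzyme of auxin synthesis from tryptophan, was at 13.8 ± 0.167 CPM in the margin and 3.08 ± 0.179 in the center (2.15 ± 0.16, adjusted p = 1.51e-08).

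The gene most reduced in the Col-0 margin was JKD, for a zinc finger protein known from root patterning, with few reads there: the ratio of center to margin was 131, with a counting interval of 23.2 to 5210 (adjusted p = 4.21e-07). MLP28, of the major latex protein family, was at 4.98 ± 2.5 CPM in the margin and 132 ± 8.4 in the center (-4.66 ± 0.18, adjusted p = 3.08e-13). Also lower were the lectin gene JAL23 (-4.36 ± 0.96, adjusted p = 0.00453), the peptide hormone gene RGF6 (-3.72 ± 0.36, adjusted p = 5.89e-07) and LSH10 of the ALOG family (-3.68 ± 0.19, adjusted p = 5.39e-11). The cytochrome P450 gene CYP708A3 (-3.67 ± 0.27, adjusted p = 1.07e-08), the myrosinase-binding protein gene MBP2 (-3.52 ± 0.55, adjusted p = 1.88e-04) and the aspartate kinase gene AK3 (-3.34 ± 0.38, adjusted p = 4.56e-06) were lower as well. TCP4 (0.47 ± 0.094, adjusted p = 0.00216) and TCP10 (0.38 ± 0.092, adjusted p = 0.00966) were higher in the margin, the latter not without the Col-0 center library 3. The other miR319-regulated TCP genes did not pass the test, nor did that list (adjusted p = 0.0565, adjusted p = 0.032 with the leaf pool as a block). All 3 other CIN-class TCP genes, which lack the miR319 site, were higher in the margin, 3 adjusted over the list alone, with TCP5 at 1.22 ± 0.17, adjusted p = 7.47e-05 and TCP17 at 1.56 ± 0.28, adjusted p = 6.59e-04. Their list passed the test (adjusted p = 7.77e-06, adjusted p = 0.0355 with an estimated correlation).

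The 24 mitotic genes lower in the margin, 28 adjusted over the list alone, included MAP65-3, needed for cytokinesis (-0.88 ± 0.12, adjusted p = 6.16e-05). The list had a median of -0.73 (adjusted p = 2.5e-19, adjusted p = 0.101 with an estimated correlation). Of 22 DNA replication genes only CDC45 was lower (-0.46 ± 0.15, adjusted p = 0.0465), none adjusted over the list alone, and the list did not pass (adjusted p = 0.472). 3 of 10 GRF and GIF growth regulator genes were lower, 3 adjusted over the list alone, GRF4 at -0.47 ± 0.12, adjusted p = 0.015 and GRF9 at -1.21 ± 0.34, adjusted p = 0.0227, while the list did not pass (adjusted p = 0.0522). No endoreduplication gene was called (adjusted p = 0.683). Of the 3 boundary and KNOX genes tested, 1 was lower in the margin and 3 adjusted over the list alone, with a median of -1.64 (adjusted p = 0.00299, adjusted p = 0.101 with an estimated correlation). 8 of 25 light harvesting and photosystem genes were higher in the margin, 20 adjusted over the list alone, among them PSAD1 (0.28 ± 0.075, adjusted p = 0.0172) and LHCB5 (0.28 ± 0.079, adjusted p = 0.0232). That list had a median of 0.27 (adjusted p = 4.77e-08, adjusted p = 0.428 with an estimated correlation).

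6 of 9 phloem genes were higher in the Col-0 margin and 1 lower (7 and 1 adjusted over the list alone). The sugar exporter gene SWEET11 was higher by 1.16 ± 0.14, adjusted p = 1.14e-05 and the proton pump gene AHA3 by 0.66 ± 0.084, adjusted p = 1.94e-05. The list was higher (adjusted p = 3.74e-05, adjusted p = 0.12 with an estimated correlation). 3 of 5 guard cell genes were higher, 4 adjusted over the list alone, including the potassium channel gene KAT1 (0.71 ± 0.10, adjusted p = 7.44e-05) and GC1 (0.84 ± 0.14, adjusted p = 5.22e-04), with adjusted p = 3.02e-04, adjusted p = 0.101 with an estimated correlation. 5 of 13 stomatal lineage genes were lower, 5 adjusted over the list alone, such as the receptor gene TMM (-0.45 ± 0.081, adjusted p = 7.78e-04) and the polarity gene BASL (-0.82 ± 0.17, adjusted p = 0.00315), while the list did not pass (adjusted p = 0.0637). Among 14 xylem genes XCP1, for a protease of tracheary elements, was lower (-0.58 ± 0.11, adjusted p = 0.00111), the only member also when adjusted over the list alone (adjusted p = 0.304). Of 9 procambium and HD-ZIP III genes TMO5 was higher (0.69 ± 0.14, adjusted p = 0.00187) and ATHB15 lower (-0.41 ± 0.075, adjusted p = 0.001), also adjusted over the list alone (adjusted p = 0.852).

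Trichome genes had 2 higher and 1 lower of 9 in the Col-0 margin, also adjusted over the list alone. Their median was 0.05 and their mean -0.25, with adjusted p = 0.684. MYB23 was higher (0.96 ± 0.19, adjusted p = 0.00176) and EGL3 lower (-1.07 ± 0.24, adjusted p = 0.00512). Abaxial identity genes had 1 higher and 2 lower of 9 (2 and 3 adjusted over the list alone), with KAN2 at 0.65 ± 0.19, adjusted p = 0.0271 and YAB5 at -0.96 ± 0.13, adjusted p = 3.1e-05 (adjusted p = 0.632 for the list). No gene of margin and lamina outgrowth was called (adjusted p = 0.664). Of the shoot apical meristem genes only the receptor gene CLV1 had enough reads to be tested (0.31 ± 0.071, adjusted p = 0.00686). Of 16 clock genes 2 were higher, also adjusted over the list alone, RVE4 by 0.32 ± 0.08, adjusted p = 0.0104 and LNK1 by 0.30 ± 0.078, adjusted p = 0.0161 (adjusted p = 0.0163, adjusted p = 0.101 with an estimated correlation). No wounding, touch and cold gene was called (adjusted p = 0.304, adjusted p = 0.0197 with the leaf pool as a block), nor any senescence gene (adjusted p = 0.852). Of 30 lists 9 passed with the preset correlation and 1 with an estimated one.

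3 of 13 genes of auxin synthesis and transport were higher in the Col-0 margin and 3 lower (4 and 5 adjusted over the list alone, adjusted p = 0.852). Besides TAA1 the auxin synthesis gene YUC2 was higher (1.76 ± 0.23, adjusted p = 3.18e-05), and the auxin importer genes LAX3 (-2.74 ± 0.20, adjusted p = 6.23e-09) and LAX2 (-0.64 ± 0.091, adjusted p = 7.47e-05) were lower. IAA7 (-0.33 ± 0.069, adjusted p = 0.00282) and IAA19 (-0.70 ± 0.16, adjusted p = 0.00591) were the 2 auxin-response repressor genes called among 13 Aux/IAA genes, the same number adjusted over the list alone (adjusted p = 0.559). No SAUR61 to SAUR68 gene was called (adjusted p = 0.927). 3 of 11 cytokinin genes were higher, and 3 higher and 3 lower when adjusted over the list alone (adjusted p = 0.439). They included the cytokinin oxidase gene CKX5 (2.25 ± 0.37, adjusted p = 3.13e-04) and ARR7 (0.57 ± 0.12, adjusted p = 0.00297). The gibberellin synthesis gene GA20OX1 was lower (-0.97 ± 0.27, adjusted p = 0.0208), 1 member of 4 also adjusted over the list alone (adjusted p = 0.67).

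Glucosinolate genes, for defense compounds of the cabbage family, had 4 members higher and 7 lower of 14, also adjusted over the list alone, with a median of -0.66 (adjusted p = 4.77e-08, adjusted p = 0.169 with an estimated correlation). CYP79B2 (1.38 ± 0.27, adjusted p = 0.00174) and CYP79B3 (0.96 ± 0.24, adjusted p = 0.0121), of the indole branch, were higher in the margin. MYB29 (-2.4 ± 0.19, adjusted p = 2.7e-08) and CYP79F1 (-3.09 ± 0.31, adjusted p = 1.01e-06), of the aliphatic branch, were lower. LDOX of anthocyanin synthesis was lower (-2.25 ± 0.49, adjusted p = 0.00426), the only member called of 8 flavonoid genes, also adjusted over the list alone (adjusted p = 0.0816, adjusted p = 8.58e-04 with the leaf pool as a block). 1 jasmonate synthesis gene of 14, AOC4, was lower (-0.56 ± 0.13, adjusted p = 0.00622), also adjusted over the list alone (adjusted p = 0.852), and no jasmonate response gene was called (adjusted p = 0.78). Of 8 known targets of CIN-class TCPs the homeodomain gene HAT2 was higher (0.54 ± 0.17, adjusted p = 0.0491), 1 member also adjusted over the list alone (adjusted p = 0.195, adjusted p = 0.0197 with the leaf pool as a block).

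**Figure D3:**
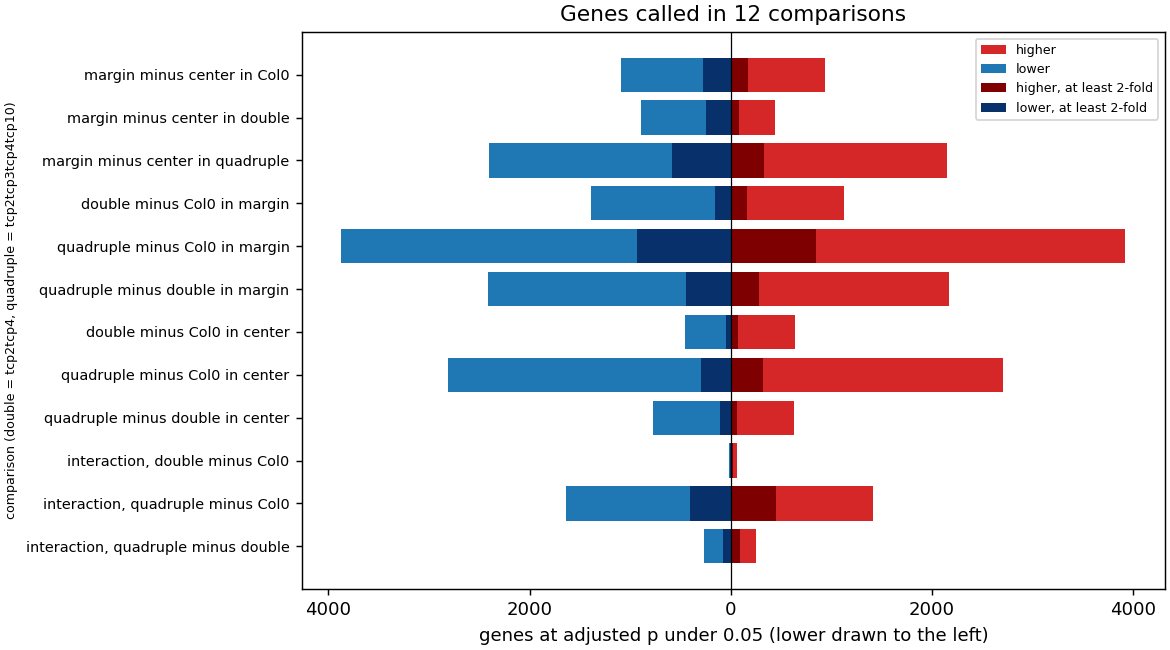
Number of genes called at an adjusted p under 0.05 in each of 12 comparisons, with the part that changed at least 2-fold in the darker shade.

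In the double mutant the same contrast asked what was left of the difference between margin and center when TCP2 and TCP4 were reduced. The mitotic list did not pass the test there, with 0 of 31 members called and a median of 0.06 (adjusted p = 0.569). Nor did light harvesting genes, with 0 of 25 called and a median of 0.03 (adjusted p = 0.3). In all 1334 genes were called, 439 higher and 895 lower in the margin, of which 86 and 242 changed at least 2-fold. With the leaf pool as a block 3041 were called. DES1 (2.58 ± 0.23), PHT1;4 (2.5 ± 0.40), AIR3 (2.15 ± 0.15) and ELI3-1, for an alcohol dehydrogenase induced by pathogens (2.46 ± 0.12), were most raised in the margin. JKD (-4.47 ± 0.43), MLP28 (-3.23 ± 0.14) and the pathogen-responsive genes PCC1 (-3.36 ± 0.35) and LURP1 (-3.31 ± 0.53) were most reduced. TCP10 was higher in the margin (0.52 ± 0.092), as was TCP4 (0.44 ± 0.13).

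The 3 other CIN-class TCP genes were all higher in the double mutant margin, also adjusted over the list alone, TCP5 by 1.39 ± 0.17 and TCP17 by 2.11 ± 0.29 (adjusted p = 1.23e-08, adjusted p = 0.00266 with an estimated correlation). 5 of 14 xylem genes were lower, 7 adjusted over the list alone, among them XCP1 (-0.93 ± 0.10) and the secondary wall cellulose synthase gene CESA8 (-0.80 ± 0.14), with adjusted p = 7.6e-06, adjusted p = 0.024 with an estimated correlation. Glucosinolate genes had 2 higher and 7 lower (4 and 7 adjusted over the list alone), MYB29 at -1.96 ± 0.17 and CYP79F1 at -2.47 ± 0.29 (adjusted p = 2.69e-07, adjusted p = 0.182 with an estimated correlation). Of 30 lists 11 passed with the preset correlation and 2 with an estimated one. The count was 842 without the margin library 1 and 864 without the center library 2, and was 764 with only the 6 libraries compared in the fit.

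In the quadruple mutant the contrast of margin with center took 4552 genes, 25.6% of those tested, and mitotic genes were higher in the margin. 2151 genes were higher and 2401 lower in the margin, of which 329 and 584 changed at least 2-fold, and 6441 were called with the leaf pool as a block. 29 of 31 mitotic genes were higher, the same number adjusted over the list alone, with a median of 0.87 (adjusted p = 1.37e-23, adjusted p = 0.0307 with an estimated correlation). MAP65-3 was higher by 1.2 ± 0.10 and the cytokinesis syntaxin gene KNOLLE by 1.2 ± 0.12. 7 of 10 GRF and GIF genes were higher, also adjusted over the list alone, such as GRF1 (0.93 ± 0.10), with adjusted p = 1.06e-05, adjusted p = 0.00403 with an estimated correlation. The genes most raised were DES1 (3.23 ± 0.29), ABCG13, a transporter gene of cuticle lipids (2.79 ± 0.23), the nitrile specifier gene NSP4 (2.52 ± 0.24) and CYP708A1 (2.5 ± 0.34). The most reduced were LURP1 (-5.19 ± 0.73), the amino acid transporter gene SIAR1 (-4.96 ± 0.40), BCAT4 of methionine chain elongation (-4.4 ± 0.42) and JKD (-4.32 ± 0.34). TCP10 (0.85 ± 0.15) and TCP24 (0.28 ± 0.07) were higher in the margin, the latter not without the margin library 3.

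Aux/IAA and SAUR61 to SAUR68 genes were lower in the quadruple mutant margin than in its center. 11 of 13 Aux/IAA genes were lower, 12 adjusted over the list alone, IAA7 at -1.31 ± 0.068 and IAA19 at -3.33 ± 0.19 (adjusted p = 4.67e-16, adjusted p = 9.72e-04 with an estimated correlation). All 6 SAUR61 to SAUR68 genes tested were lower, also adjusted over the list alone, SAUR62 at -1.47 ± 0.21 (adjusted p = 9.81e-07, adjusted p = 0.0442 with an estimated correlation). 10 of 14 glucosinolate genes were lower, 11 adjusted over the list alone, MYB29 at -2.69 ± 0.16 and CYP83A1 at -2.6 ± 0.16 (adjusted p = 1.19e-19, adjusted p = 0.0226 with an estimated correlation). 21 of 25 light harvesting genes were lower, 23 adjusted over the list alone, with a median of -0.32 (adjusted p = 2.65e-07, adjusted p = 0.366 with an estimated correlation).

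Xylem and phloem lists were lower and stomatal lineage and trichome lists higher in the quadruple mutant margin. 12 of 14 xylem genes were lower, also adjusted over the list alone, XCP1 at -1.46 ± 0.10 and XCP2 at -1.05 ± 0.078 (adjusted p = 1.45e-13, adjusted p = 4.12e-04 with an estimated correlation). 6 of 9 phloem genes were lower, 8 adjusted over the list alone, including the sieve element gene SEOR1 (-1.08 ± 0.10), with adjusted p = 2.65e-07, adjusted p = 0.0442 with an estimated correlation. 9 of 13 stomatal lineage genes were higher, also adjusted over the list alone, with SPCH, which starts the lineage, at 1.05 ± 0.088 and TMM at 0.71 ± 0.072 (adjusted p = 9.87e-09, adjusted p = 0.00932 with an estimated correlation). 7 of 9 trichome genes were higher, also adjusted over the list alone, GL2 by 1.35 ± 0.11 and MYB23 by 1.41 ± 0.15 (adjusted p = 1.16e-07, adjusted p = 0.00672 with an estimated correlation). 4 of 5 margin and lamina outgrowth genes were higher, also adjusted over the list alone, AS1 by 0.75 ± 0.10 and WOX1 by 1.27 ± 0.20 (adjusted p = 5.57e-05, adjusted p = 0.021 with an estimated correlation). The other CIN-class TCP list was higher, with a median of 1.36 (adjusted p = 5.57e-05, adjusted p = 0.021 with an estimated correlation). Of 30 lists 15 passed with the preset correlation and 11 with an estimated one.

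**Figure D4:**
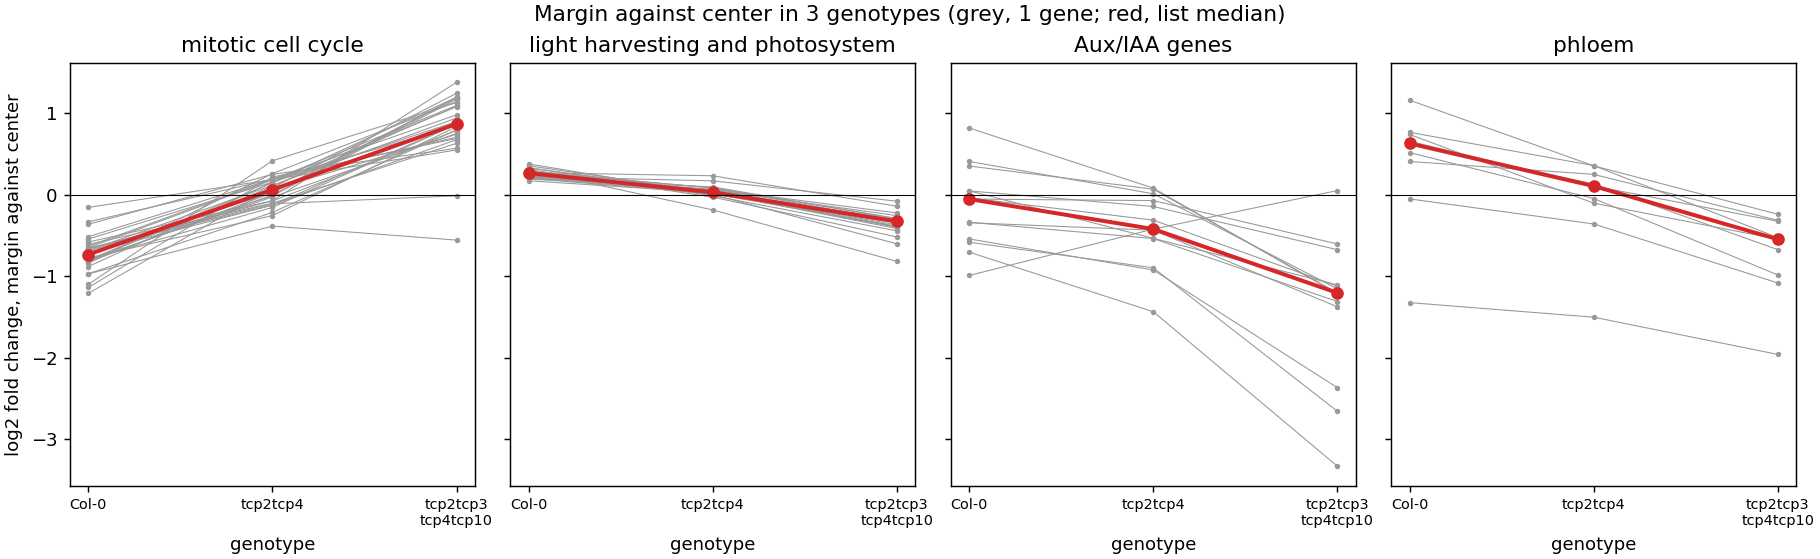
Log2 fold change of margin against center in Col-0, tcp2tcp4 and tcp2tcp3tcp4tcp10 for each member of 4 gene lists (grey) and the list median (red).

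Comparing the double mutant with Col-0 in the margin asked what the loss of TCP2 and TCP4 changed there. The GRF and GIF list was higher in the mutant margin. So were the mitotic and stomatal lineage lists, and the light harvesting and phloem lists were lower, but these did not pass with an estimated correlation. 2513 genes (14.1%) were called, 1125 higher and 1388 lower, of which 161 and 152 changed at least 2-fold. The clock-linked genes COR27 (3.15 ± 0.75), JMJD5 (3.03 ± 0.52) and FKF1 (2.34 ± 0.48) and the gene E13L3, for a glucanase-like protein (2.75 ± 0.25), were most raised. BHLH100 (-4.77 ± 0.68), the mutated TCP2 (-2.57 ± 0.086) and TCP4 (-2.43 ± 0.11) and the camalexin synthesis gene CYP71A13 (-2.24 ± 0.21) were most reduced. TCP3 (-0.05 ± 0.29), TCP10 (0.19 ± 0.09) and TCP24 (0.10 ± 0.073) did not pass the test. The miR319-regulated list was lower, with its 2 mutated members called (adjusted p = 8.49e-22, adjusted p = 9.16e-06 with an estimated correlation).

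21 of 31 mitotic genes were higher in the double mutant margin, 27 adjusted over the list alone, MAP65-3 by 0.90 ± 0.12 and the cyclin gene CYCB1;1 by 1.24 ± 0.21 (adjusted p = 9.16e-16, adjusted p = 0.143 with an estimated correlation). 5 of 10 GRF and GIF genes were higher, also adjusted over the list alone, with GRF3 at 0.90 ± 0.13 and GRF4 at 0.65 ± 0.12 (adjusted p = 5.94e-04, adjusted p = 0.0255 with an estimated correlation). 5 stomatal lineage genes were higher (7 higher and 1 lower adjusted over the list alone), TMM by 0.80 ± 0.079 and SPCH by 0.91 ± 0.11 (adjusted p = 1.33e-04, adjusted p = 0.0904 with an estimated correlation). 23 of 25 light harvesting genes were lower, 25 adjusted over the list alone, such as LHCB4.2 (-0.55 ± 0.10), with a median of -0.41 (adjusted p = 2.27e-20, adjusted p = 0.161 with an estimated correlation). 6 of 9 phloem genes were lower, also adjusted over the list alone, AHA3 at -0.60 ± 0.084 and the sucrose transporter gene SUC2 at -0.63 ± 0.10 (adjusted p = 9.38e-06, adjusted p = 0.143 with an estimated correlation).

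3 of 8 known TCP targets were lower in the double mutant margin (1 higher and 5 lower adjusted over the list alone), including the cell cycle inhibitor gene KRP1 (-0.85 ± 0.15) and HAT2 (-0.91 ± 0.18), with adjusted p = 0.00278, adjusted p = 0.0904 with an estimated correlation. 7 of 16 clock genes were higher and 7 lower, also adjusted over the list alone (adjusted p = 0.808). PRR5 (1.72 ± 0.24) and TOC1 (1.04 ± 0.23), which peak after midday, were higher, and the morning genes PRR9 (-1.36 ± 0.20) and RVE4 (-0.52 ± 0.081) were lower. The cold-induced gene COR15A was higher (1.53 ± 0.19). The count was 1519 without the double mutant margin library 1. Both libraries rich in reads aligned to several places, at 16.0% and 8.60%, belonged to the groups compared here, and 1954 genes were called without them.

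The quadruple mutant against Col-0 in the margin, the comparison with the most calls, asked what the loss of 4 miR319-regulated TCP genes changed at the leaf edge. Mitotic, GRF and GIF, trichome and lamina outgrowth genes were higher in the mutant margin. Aux/IAA and phloem genes were lower. 7796 genes, 43.9% of those tested, were called, 3925 higher and 3871 lower, of which 851 and 927 changed at least 2-fold. Of the 8 genes most raised, the acyltransferase gene PEL3 of cutin synthesis went from 17.2 ± 3.3 to 176 ± 15.8 CPM (3.33 ± 0.21, adjusted p = 1.09e-10) and MLP28 from 4.98 ± 2.5 to 94.2 ± 6.46 CPM (4.17 ± 0.18, adjusted p = 8.61e-13). E13L3 (4.51 ± 0.21, adjusted p = 1.64e-12), NSP4 (3.96 ± 0.31, adjusted p = 2.88e-09) and CYP708A1 (3.93 ± 0.45, adjusted p = 4.53e-07) were raised too. The transporter gene ABCG8 (3.89 ± 0.34, adjusted p = 1.27e-08), the methionine sulfoxide reductase gene MSRB9 (3.59 ± 0.44, adjusted p = 9.93e-07) and CYP77B1 (3.35 ± 0.20, adjusted p = 8.5e-11) were the others.

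Among the 8 genes most reduced in the quadruple mutant margin, ELI3-1 went from 165 ± 8.65 to 2.36 ± 0.491 CPM (-6.14 ± 0.14, adjusted p = 4.38e-17). The receptor kinase genes CRK21 (-5.6 ± 0.20, adjusted p = 3.08e-14) and CRK22 (-4.96 ± 0.18, adjusted p = 4.12e-14), the cell death regulator gene ACD6 (-4.4 ± 0.36, adjusted p = 3.91e-09) and CYP79B3 (-4.24 ± 0.33, adjusted p = 2.64e-09) were lower. AIR3 was lower (-4.0 ± 0.14, adjusted p = 2.72e-14), and GASA6, of a gibberellin-regulated peptide family, went from 221 ± 6.14 to 13.7 ± 3.03 CPM (-4.0 ± 0.19, adjusted p = 2.95e-12). BHLH100 had few reads left in the mutant: the ratio of Col-0 to mutant was 182, with a counting interval of 32.0 to 7230 (adjusted p = 9.81e-07). TCP2 (-2.84 ± 0.085, adjusted p = 2.34e-15), TCP3 (-2.69 ± 0.39, adjusted p = 9e-06), TCP4 (-2.21 ± 0.10, adjusted p = 1.78e-12) and TCP10 (-3.17 ± 0.11, adjusted p = 2.43e-14) were lower. The miR319-regulated list had 4 members lower and 1 higher (adjusted p = 2.07e-17, adjusted p = 5.19e-05 with an estimated correlation). No other CIN-class TCP gene was called (adjusted p = 0.9).

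30 of 31 mitotic genes were higher in the quadruple mutant margin, the same number adjusted over the list alone, with a median of 1.43 (adjusted p = 1.56e-23, adjusted p = 0.0406 with an estimated correlation). MAP65-3 was higher by 1.87 ± 0.11, adjusted p = 8.5e-11 and the kinesin gene POK2, which guides the division plane, by 1.88 ± 0.12, adjusted p = 2.9e-10. The DNA replication list did not pass (adjusted p = 0.111). 9 of 10 GRF and GIF genes were higher, also adjusted over the list alone, GRF3 by 1.58 ± 0.12, adjusted p = 2.62e-09 and GRF4 by 1.21 ± 0.11, adjusted p = 2.79e-08 (adjusted p = 1.95e-07, adjusted p = 0.00133 with an estimated correlation). All 5 genes of margin and lamina outgrowth tested were higher, also adjusted over the list alone, AS1 by 1.11 ± 0.11, adjusted p = 4.39e-08 and AS2 by 1.7 ± 0.17, adjusted p = 1.07e-07 (adjusted p = 5.41e-05, adjusted p = 0.0164 with an estimated correlation). JAG, a lamina growth gene, had 0 reads in the Col-0 margin and was at least 17.8-fold higher in the mutant.

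Known targets of CIN-class TCPs had 6 members lower and 2 higher of 8 in the quadruple mutant margin, also adjusted over the list alone (adjusted p = 0.00835, adjusted p = 0.0861 with an estimated correlation). KRP1 (-1.72 ± 0.16, adjusted p = 2.63e-08) and HAT2 (-2.08 ± 0.20, adjusted p = 3.18e-08) were lower, and AS1 and the light-signaling gene HY5 (0.67 ± 0.17, adjusted p = 0.00313) were higher. 12 of 13 Aux/IAA genes were lower and 1 higher, also adjusted over the list alone (adjusted p = 6.81e-07, adjusted p = 0.0164 with an estimated correlation). IAA1 was lower, at -2.81 ± 0.20, adjusted p = 7.93e-10 and IAA2 at -2.58 ± 0.19, adjusted p = 1.55e-09, and IAA30 was higher (2.42 ± 0.55, adjusted p = 0.00112). All 6 SAUR61 to SAUR68 genes tested were lower, also adjusted over the list alone, SAUR62 at -2.4 ± 0.20, adjusted p = 4.39e-09 (adjusted p = 9.43e-07, adjusted p = 0.0576 with an estimated correlation).

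All 9 phloem genes were lower in the quadruple mutant margin, also adjusted over the list alone, SUC2 at -2.3 ± 0.11, adjusted p = 2.76e-12 and AHA3 at -1.83 ± 0.088, adjusted p = 2.95e-12 (adjusted p = 1.42e-16, adjusted p = 0.00629 with an estimated correlation). 6 of 9 procambium and HD-ZIP III genes were higher and 1 lower, also adjusted over the list alone (adjusted p = 0.00252, adjusted p = 0.0861 with an estimated correlation). REV was higher by 0.96 ± 0.078, adjusted p = 4.4e-09 and the auxin response factor gene MP by 1.14 ± 0.12, adjusted p = 2.21e-07, and TMO5 was lower (-0.62 ± 0.13, adjusted p = 4.89e-04). Stomatal lineage genes had 8 higher and 2 lower of 13, also adjusted over the list alone (adjusted p = 0.00105, adjusted p = 0.0861 with an estimated correlation). SPCH was higher by 1.93 ± 0.10, adjusted p = 1.29e-11 and TMM by 1.24 ± 0.077, adjusted p = 1.18e-10, while SCRM2 (-0.75 ± 0.076, adjusted p = 9.72e-08) and EPFL9 (-0.51 ± 0.083, adjusted p = 3.82e-05) were lower. 4 of 5 guard cell genes were lower, also adjusted over the list alone, KAT1 at -2.18 ± 0.11, adjusted p = 8.74e-12 (adjusted p = 0.00142, adjusted p = 0.0861 with an estimated correlation). Trichome genes had 7 higher and 2 lower, also adjusted over the list alone, with GL2 at 1.91 ± 0.12, adjusted p = 1.57e-10, EGL3 at 2.41 ± 0.20, adjusted p = 5.99e-09 and the inhibitor gene TRY at -0.66 ± 0.19, adjusted p = 0.00798 (adjusted p = 1.65e-04, adjusted p = 0.0164 with an estimated correlation).

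All 25 light harvesting and photosystem genes were lower in the quadruple mutant margin, also adjusted over the list alone, with a median of -0.99 (adjusted p = 3.65e-28, adjusted p = 0.0623 with an estimated correlation). PSAE1 was lower, at -1.03 ± 0.073, adjusted p = 6.74e-10. 10 of 14 glucosinolate genes were lower, 12 adjusted over the list alone, CYP83B1 at -2.69 ± 0.16, adjusted p = 5.91e-11 and MYB34 at -2.55 ± 0.18, adjusted p = 7.74e-10 (adjusted p = 2.15e-07, adjusted p = 0.139 with an estimated correlation). Of the jasmonate synthesis genes 6 were lower and 3 higher, also adjusted over the list alone (adjusted p = 0.403), with LOX2, the chloroplast lipoxygenase gene and a known TCP target, at -3.15 ± 0.32, adjusted p = 8.17e-08 and LOX6 at 0.53 ± 0.10, adjusted p = 2.32e-04.

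Clock genes of the quadruple mutant margin had 6 higher and 6 lower, also adjusted over the list alone (adjusted p = 0.952), with PRR5 at 1.77 ± 0.23, adjusted p = 2.87e-06 and PRR9 at -2.19 ± 0.21, adjusted p = 3.88e-08. In all 17 of 30 lists passed with the preset correlation and 7 with an estimated one. The lines were placed in the greenhouse 2 days apart, so plant age differed with genotype.

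Between the quadruple and the double mutant the margin comparison asked what the further loss of TCP3 and TCP10 changed. Mitotic, GRF and GIF and trichome genes were higher in the quadruple mutant, and phloem and Aux/IAA genes were lower. 4585 genes were called, 2173 higher and 2412 lower, of which 286 and 442 changed at least 2-fold. TCP10 (-3.35 ± 0.11) and TCP3 (-2.64 ± 0.38) were lower in the quadruple mutant, and TCP2 (-0.27 ± 0.10) and TCP4 (0.21 ± 0.11) did not pass the test (adjusted p = 3.77e-07, adjusted p = 0.00227 with an estimated correlation for the list). The glycine-rich protein gene GRP3S (3.88 ± 0.37), ABCG8 (2.84 ± 0.28), CYP708A1 (2.49 ± 0.34) and NSP4 (2.36 ± 0.24) were most raised. ELI3-1 (-4.59 ± 0.15), CRK21 (-4.08 ± 0.23) and CRK22 (-3.73 ± 0.20) were, with TCP10, most reduced. 28 of 31 mitotic genes were higher in the quadruple mutant, also adjusted over the list alone, POK2 by 1.15 ± 0.11 (adjusted p = 1.05e-20, adjusted p = 0.0421 with an estimated correlation). So were 8 GRF and GIF genes (adjusted p = 4.05e-08, adjusted p = 0.0018 with an estimated correlation) and 7 trichome genes (adjusted p = 8.85e-06, adjusted p = 0.0138 with an estimated correlation), with the same numbers adjusted over each list alone. 5 lamina outgrowth genes were higher, also adjusted over the list alone (adjusted p = 3.61e-06, adjusted p = 0.0025 with an estimated correlation).

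11 Aux/IAA genes were lower and 1 higher in the quadruple than in the double mutant margin, also adjusted over the list alone, with IAA1 at -1.96 ± 0.21 (adjusted p = 3.46e-09, adjusted p = 0.0025 with an estimated correlation). All 9 phloem genes were lower, also adjusted over the list alone, the lectin gene PP2-A1 at -1.67 ± 0.10 and SUC2 at -1.67 ± 0.11 (adjusted p = 8.59e-20, adjusted p = 0.0025 with an estimated correlation). Of 30 lists 19 passed with the preset correlation and 11 with an estimated one. Of the clock genes LHY (1.55 ± 0.33) and RVE8 (1.13 ± 0.23) were higher.

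The double mutant against Col-0 in the center asked what the loss of TCP2 and TCP4 changed in the inner leaf. Clock genes went both ways there, and no mitotic gene was called. In all 1093 genes were called, of which 636 were higher and 457 lower, 74 and 48 of them at least 2-fold. TCP2 (-2.96 ± 0.092) and TCP4 (-2.4 ± 0.11) were lower, as was the miR319-regulated list (adjusted p = 5.14e-29, adjusted p = 1.87e-06 with an estimated correlation), while TCP3 (0.63 ± 0.30) and TCP10 (0.05 ± 0.093) did not pass. COR27 (3.17 ± 0.81), SIAR1 (2.61 ± 0.36), FKF1 (2.23 ± 0.50) and the proline dehydrogenase gene ERD5 (1.85 ± 0.32) were most raised. ELI3-1 (-2.46 ± 0.12) and the light stress gene ELIP1 (-1.26 ± 0.29) were, with TCP2 and TCP4, most reduced. The mitotic list was lower with a median of -0.14 (adjusted p = 0.0466, adjusted p = 0.86 with an estimated correlation, adjusted p = 0.0513 with the repetition number as a block). GRF3 was higher (0.64 ± 0.13). 2 known TCP targets were lower (1 higher and 3 lower adjusted over the list alone), ARR16 at -1.05 ± 0.17 and KRP1 at -0.98 ± 0.17 (adjusted p = 0.0285, adjusted p = 0.406 with an estimated correlation).

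Clock genes of the double mutant center had 6 higher and 2 lower (8 and 6 adjusted over the list alone, adjusted p = 0.171), with PRR5 at 1.62 ± 0.24, GI at 0.80 ± 0.13 and PRR9 at -0.87 ± 0.20. COR15A was higher (1.58 ± 0.19). Of 30 lists 8 passed with the preset correlation and 1, holding the mutated genes, with an estimated one. The count was 462 without the Col-0 center library 1, 659 and 626 without the double mutant center library 1 or 2, and 674 with only the 6 libraries compared.

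The quadruple mutant against Col-0 in the center asked the same of the inner leaf. 5520 genes (31.1%) were called, 2706 higher and 2814 lower, of which 323 and 298 changed at least 2-fold. The procambium and HD-ZIP III list was higher in the mutant center. The phloem and light harvesting lists were lower, but not with an estimated correlation. The mitotic list did not pass the test. ASN1, an asparagine synthetase gene known to respond to sugar depletion, was most raised (3.38 ± 0.60, adjusted p = 2.4e-04). GRP3S (3.29 ± 0.28, adjusted p = 5.38e-08), SIAR1 (3.14 ± 0.34, adjusted p = 9.2e-07), OFP12 of the OVATE family (2.69 ± 0.21, adjusted p = 1.77e-08), FKF1 (2.33 ± 0.48, adjusted p = 9.2e-04) and ERD5 (2.3 ± 0.30, adjusted p = 1.06e-05) followed. DOT1, a gene named for its vein pattern mutant, went from 6.12 ± 0.702 to 33.4 ± 4.1 CPM (2.45 ± 0.15, adjusted p = 4.8e-10). COR27 was also among the 8 most raised (2.79 ± 0.82, adjusted p = 0.0132), but not without the Col-0 center library 3 or the quadruple mutant center library 3.

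CRK21 went from 41.8 ± 4.1 CPM in the Col-0 center to 0.549 ± 0.395 in the quadruple mutant (-6.31 ± 0.26, adjusted p = 6.67e-13). CRK22 (-5.44 ± 0.23, adjusted p = 7.9e-13), ELI3-1 (-5.21 ± 0.16, adjusted p = 1.1e-14), AIR3 (-3.98 ± 0.24, adjusted p = 4.71e-10) and CYP79B2 (-2.89 ± 0.40, adjusted p = 1.91e-05) were also among the 8 most reduced. So were TCP10 (-3.63 ± 0.12, adjusted p = 4.29e-14), TCP2 (-3.14 ± 0.088, adjusted p = 2.54e-15) and LOX2, which went from 376 ± 57.3 to 41.4 ± 11.1 CPM (-3.18 ± 0.33, adjusted p = 5.63e-07). TCP3 (-2.24 ± 0.42, adjusted p = 4.26e-04) and TCP4 (-2.0 ± 0.10, adjusted p = 4.97e-11) were lower and TCP24 did not pass (0.02 ± 0.072, adjusted p = 0.903), with adjusted p = 2.14e-35, adjusted p = 6.89e-07 with an estimated correlation for the list.

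Of the mitotic genes 2 were higher and 3 lower in the quadruple mutant center (1 and 1 adjusted over the list alone), with a median of -0.21 (adjusted p = 0.13). POK2 was higher (0.43 ± 0.12, adjusted p = 0.00934) and CYCA2;3 lower (-0.45 ± 0.10, adjusted p = 0.00154). 4 GRF and GIF genes were higher, also adjusted over the list alone, GRF3 by 1.1 ± 0.12, adjusted p = 8.04e-07 (adjusted p = 0.07). Known TCP targets had 2 higher and 4 lower, also adjusted over the list alone, with ARR16 at -1.71 ± 0.17, adjusted p = 3.06e-07 and KRP1 at -1.37 ± 0.17, adjusted p = 3.43e-06 (adjusted p = 0.00958, adjusted p = 0.162 with an estimated correlation).

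All 9 procambium and HD-ZIP III genes were higher in the quadruple mutant center, also adjusted over the list alone, REV by 0.65 ± 0.078, adjusted p = 3.73e-06 and PHB by 0.51 ± 0.073, adjusted p = 2.81e-05 (adjusted p = 6.84e-07, adjusted p = 0.0365 with an estimated correlation). 8 of 14 xylem genes were higher, 9 adjusted over the list alone, XCP2 by 0.53 ± 0.078, adjusted p = 3.28e-05 (adjusted p = 0.00116, adjusted p = 0.0579 with an estimated correlation). 6 of 9 phloem genes were lower and 1 higher, also adjusted over the list alone, with SUC2 at -1.01 ± 0.11, adjusted p = 8.04e-07 and SEOR1 at 0.35 ± 0.10, adjusted p = 0.0101 (adjusted p = 8.21e-04, adjusted p = 0.249 with an estimated correlation). 23 of 25 light harvesting genes were lower, 24 adjusted over the list alone, PSAE1 at -0.49 ± 0.073, adjusted p = 3.89e-05 (adjusted p = 1.31e-10, adjusted p = 0.38 with an estimated correlation).

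Aux/IAA genes had 4 higher and 5 lower in the quadruple mutant center (5 and 5 adjusted over the list alone, adjusted p = 0.796), with IAA16 at 0.69 ± 0.078, adjusted p = 1.79e-06 and IAA1 at -1.25 ± 0.18, adjusted p = 2.89e-05.

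9 of 16 clock genes were higher in the quadruple mutant center and 1 lower, also adjusted over the list alone, with PRR5 at 1.88 ± 0.23, adjusted p = 4.74e-06, GI at 0.78 ± 0.13, adjusted p = 1.31e-04 and PRR9 at -1.45 ± 0.20, adjusted p = 2.02e-05 (adjusted p = 0.025, adjusted p = 0.129 with an estimated correlation). In all 10 of 30 lists passed with the preset correlation and 2 with an estimated one. The 2 included the miR319-regulated list, which holds the mutated genes.

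Between the 2 mutants the center comparison gave 1409 calls, 633 higher and 776 lower in the quadruple mutant, of which 60 and 106 changed at least 2-fold. GRP3S (3.18 ± 0.29), the clock genes LHY (2.29 ± 0.36) and RVE8 (1.38 ± 0.22) and the glucose-6-phosphate dehydrogenase gene G6PD3 (1.37 ± 0.16) were most raised. CRK21 (-5.25 ± 0.30), CRK22 (-4.18 ± 0.27), TCP10 (-3.68 ± 0.12) and AIR3 (-3.16 ± 0.28) were most reduced. TCP3 was lower (-2.87 ± 0.40) and TCP4 did not pass (0.40 ± 0.13), with adjusted p = 6.9e-15, adjusted p = 7.03e-05 with an estimated correlation for the list. 5 phloem genes were lower, 6 adjusted over the list alone, SWEET11 at -1.43 ± 0.17 (adjusted p = 2.67e-10, adjusted p = 0.0477 with an estimated correlation). 6 procambium and HD-ZIP III genes were higher, 8 adjusted over the list alone, REV by 0.47 ± 0.079 (adjusted p = 1.42e-08, adjusted p = 0.0135 with an estimated correlation). LOX2 (-2.65 ± 0.33) and MYB34 (-1.5 ± 0.22) were lower. No mitotic gene was called (adjusted p = 0.777). Of 30 lists 13 passed with the preset correlation and 3 with an estimated one. The count was 841 without the quadruple mutant center library 3, 871 without the double mutant center library 3, and 750 with only the 6 libraries compared in the fit.

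**Figure D5:**
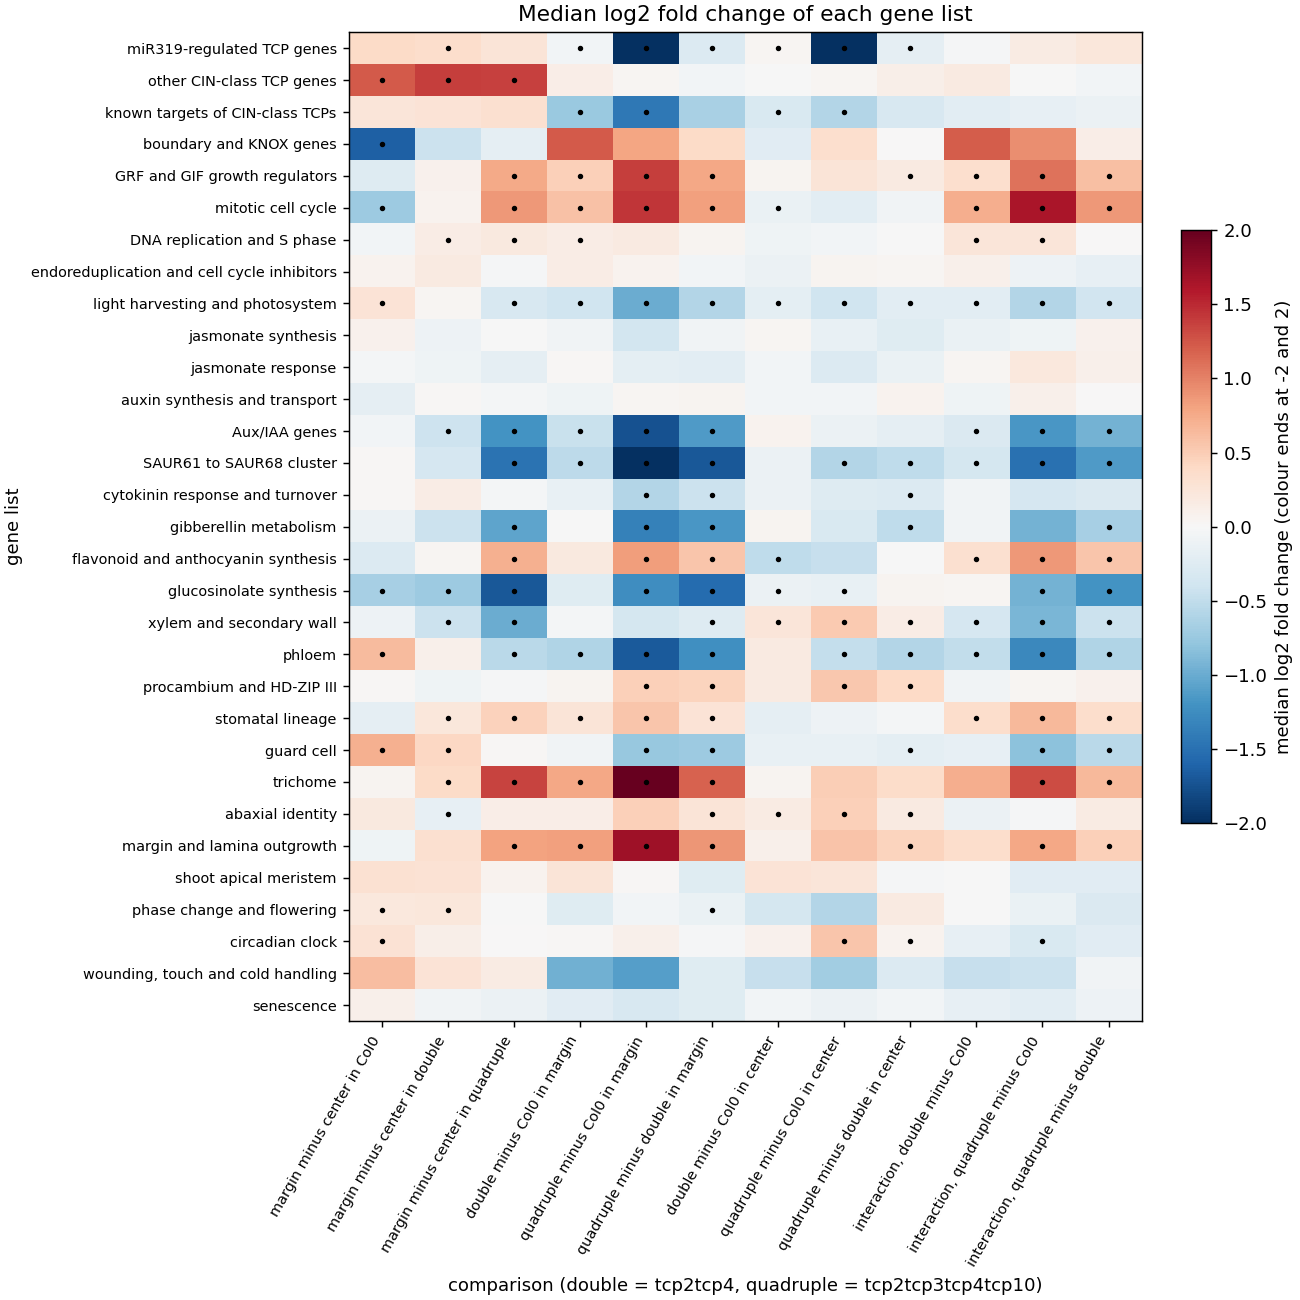
Median log2 fold change of each gene list in the 12 comparisons. A dot marks lists with an adjusted p under 0.05 in the test with a preset correlation.

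The interaction of compartment and genotype asked whether margin and center differed by other amounts in a mutant than in Col-0. For the double mutant 78 genes were called, 59 with a higher and 19 with a lower margin minus center value than in Col-0, of which 24 and 4 differed at least 2-fold. Most raised were CYP77B1 (1.92 ± 0.32), PEL3 (1.83 ± 0.30) and the cutin hydroxylase gene CYP86A4 (1.53 ± 0.34), with the Rop exchange factor gene ROPGEF6 (1.6 ± 0.28). Most reduced were the ferric reductase genes FRO3 (-1.19 ± 0.22) and FRO7 (-0.68 ± 0.14), FTIP1 (-0.84 ± 0.19) and the iron transporter gene OPT3 (-0.62 ± 0.13). The calls of CYP86A4, FTIP1, FRO7 and OPT3 were lost under 10 or more alternative settings each. 3 mitotic genes were higher in the interaction, 23 adjusted over the list alone, such as MAP65-3 (1.03 ± 0.17), and the list had a median of 0.73 (adjusted p = 3.1e-31, adjusted p = 0.0291 with an estimated correlation). TMM was the 1 stomatal lineage gene called (0.74 ± 0.11), with 7 adjusted over the list alone (adjusted p = 4.76e-10, adjusted p = 0.022 with an estimated correlation). No GRF or GIF gene was called, 1 adjusted over the list alone (adjusted p = 0.0019, adjusted p = 0.0291 with an estimated correlation), and no DNA replication gene, 6 adjusted over the list alone (adjusted p = 7.49e-06, adjusted p = 0.0291 with an estimated correlation).

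2 phloem genes were lower in the interaction of the double mutant, AHA3 (-0.55 ± 0.12) and FTIP1, and 5 adjusted over the list alone (adjusted p = 2.15e-08, adjusted p = 0.0477 with an estimated correlation). The xylem list was lower with 2 members adjusted over the list alone (adjusted p = 0.00136, adjusted p = 0.0477 with an estimated correlation). Of 30 lists 10 passed with the preset correlation and 6 with an estimated one. With the leaf pool as a block 1347 genes were called, 708 higher and 639 lower. The count was 131 with DESeq2, 175 without a low count filter, 39 with only the 12 libraries compared in the fit, and from 17 without the double mutant center library 2 to 208 without its library 1.

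For the quadruple mutant the interaction with Col-0 gave 3047 genes (17.2%), 1414 higher and 1633 lower, of which 449 and 404 differed at least 2-fold, and 4996 with the leaf pool as a block. The mitotic list was lower in the Col-0 margin, but not with an estimated correlation, and higher in that of the quadruple mutant. 29 of 31 mitotic genes were higher in the interaction, also adjusted over the list alone, with a median of 1.63 (adjusted p = 1.16e-51, adjusted p = 0.00463 with an estimated correlation). MAP65-3 was higher by 2.08 ± 0.16, adjusted p = 1.3e-07. 6 GRF and GIF genes were higher, 7 adjusted over the list alone, GRF4 by 1.07 ± 0.16, adjusted p = 8.28e-05 (adjusted p = 8.35e-06, adjusted p = 0.00356 with an estimated correlation). 8 stomatal lineage genes were higher, also adjusted over the list alone, SPCH by 1.58 ± 0.15, adjusted p = 5.51e-07 and TMM by 1.16 ± 0.11, adjusted p = 5.51e-07 (adjusted p = 3.4e-10, adjusted p = 0.00531 with an estimated correlation). The largest interactions were those of the anthocyanin genes LDOX (3.94 ± 0.64, adjusted p = 2.21e-04) and UF3GT (3.45 ± 0.54, adjusted p = 1.56e-04), MSRB9 (3.85 ± 0.64, adjusted p = 2.58e-04) and PEL3 (3.54 ± 0.28, adjusted p = 2.05e-07). PEL3 was at 17.2 ± 3.3 CPM in the margin and 40.9 ± 4.19 in the center of Col-0, and at 176 ± 15.8 and 36.0 ± 9.34 CPM in the quadruple mutant. In the other direction stood the MYB-related gene RL3 (-3.61 ± 0.39, adjusted p = 2.88e-06), the chitinase gene ChiC (-3.03 ± 0.30, adjusted p = 1.21e-06), PHT1;4 (-3.21 ± 0.77, adjusted p = 0.00608) and WRKY29 (-3.07 ± 0.81, adjusted p = 0.012). The calls of PHT1;4 and WRKY29 were lost without the quadruple mutant center library 1.

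10 Aux/IAA genes were lower in the interaction of the quadruple mutant, 12 adjusted over the list alone, IAA19 at -2.63 ± 0.26, adjusted p = 1.18e-06 and IAA7 at -0.97 ± 0.10, adjusted p = 1.18e-06 (adjusted p = 3.54e-12, adjusted p = 0.00349 with an estimated correlation). All 9 phloem genes were lower, also adjusted over the list alone, PP2-A1 at -1.5 ± 0.14, adjusted p = 4.65e-07 and SUC2 at -1.29 ± 0.15, adjusted p = 6.44e-06 (adjusted p = 2.61e-14, adjusted p = 0.00709 with an estimated correlation). 8 xylem genes were lower, also adjusted over the list alone, XCP2 at -0.95 ± 0.11, adjusted p = 7.68e-06 (adjusted p = 9.22e-08, adjusted p = 0.00349 with an estimated correlation). Of 30 lists 15 passed with the preset correlation and 6 with an estimated one.

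Between the mutants the interaction gave 515 genes, 254 higher and 261 lower in the quadruple mutant, of which 97 and 81 differed at least 2-fold, and 2009 with the leaf pool as a block. 17 mitotic genes were higher, 27 adjusted over the list alone, MAP65-3 by 1.04 ± 0.15 (adjusted p = 3.58e-34, adjusted p = 0.0196 with an estimated correlation). So were 2 GRF and GIF genes, 6 adjusted over the list alone (adjusted p = 1.29e-04, adjusted p = 0.00987 with an estimated correlation). NPC3, for a phospholipase C (1.98 ± 0.36), the cellulase gene CEL2 (1.84 ± 0.43), LDOX (2.47 ± 0.67) and UF3GT (1.94 ± 0.53) were most raised, the last 3 lost under 5 or more alternative settings each. The glucosinolate genes AKN2 (-2.17 ± 0.43) and SOT17 (-2.15 ± 0.37), IAA19 (-1.9 ± 0.27) and ELI3-1 (-1.84 ± 0.32) were most reduced. 6 Aux/IAA genes were lower, 9 adjusted over the list alone (adjusted p = 3.89e-15, adjusted p = 0.00177 with an estimated correlation), as were 2 SAUR61 to SAUR68 genes, 6 adjusted over the list alone (adjusted p = 8.43e-08, adjusted p = 0.0474 with an estimated correlation). 3 xylem genes were lower, 6 adjusted over the list alone (adjusted p = 6.62e-07, adjusted p = 0.00547 with an estimated correlation), and 3 phloem genes, 9 adjusted over the list alone (adjusted p = 6.59e-11, adjusted p = 0.0232 with an estimated correlation). Of 30 lists 14 passed with the preset correlation and 6 with an estimated one. The count was 269 without the quadruple mutant center library 2, 293 without the double mutant center library 1, 326 without the quadruple mutant margin library 3 and 331 without the double mutant margin library 2.

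Genes called in 2 comparisons were counted by direction and set against the number that independent calls would give. Against Col-0 in the margin, 2344 genes were called in both mutants: 1021 higher in both against 248.6 for independent calls, 1312 lower in both against 302.5, and 11 in opposite directions against 551.9. In the center the numbers were 987 in both, 573 higher against 96.89, 414 lower against 72.4 and 0 opposite. Both mutants were compared with the same 3 Col-0 libraries, so part of this excess may come from the shared controls; 3 libraries are too few to be split into groups of 2. Simulated libraries without any change gave a covariance of the log2 fold changes of 0.0312 in the margin and 0.0241 in the center, and at most 0 and 1 genes called in both mutants. The observed covariances were 0.229 and 0.110, and the Pearson correlations 0.760 and 0.698 against 0.565 and 0.502 in the simulation. Between margin and center, which share no libraries but may share leaf pools and so are not independent, the double mutant had 634 genes called in both (327 higher, 302 lower, 5 opposite) and the quadruple mutant 3651 (1583 higher, 1866 lower, 202 opposite against 1212 for independent calls).

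For the difference between margin and center, 1087 genes were called in both Col-0 and the quadruple mutant, of which 466 (42.9%) went in opposite directions against 259.1 for independent calls. Of those, 263 were lower in the Col-0 margin and higher in that of the quadruple mutant, and 203 the reverse. Col-0 and the double mutant shared 685 genes, 209 higher, 465 lower and 11 opposite, and the 2 mutants shared 957, of which 15 were opposite. The size of the difference was compared by a slope through the origin over genes selected in the third genotype, with a bootstrap SD over genes. Error in the values on the reference axis lowers such a slope. The slope of the double mutant on Col-0 was 0.693 ± 0.0222, that of the quadruple mutant on Col-0 0.702 ± 0.0369 and that of the quadruple on the double mutant 0.759 ± 0.0508. The median ratios over the same genes were 0.429, 1.07 and 0.654, and 62.6%, 85.2% and 67.4% of the genes had the same sign. Over all 17763 genes the Spearman correlations were 0.377, 0.0292 and 0.493 in the same order.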

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

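The test of scaling was written before its result was seen, and the other tests of explanations below were chosen after the result they bear on was seen. Differences between genotypes in how margin and center differ were the main signal set apart here. In the interaction of the double mutant with Col-0, 78 genes passed the test, and the list medians were 0.33 for GRF and GIF genes, 0.73 for mitotic genes, 0.24 for DNA replication, −0.33 for xylem, −0.50 for phloem and 0.35 for the stomatal lineage. For the quadruple mutant against Col-0 there were 3047 genes, with medians of 1.09 for GRF and GIF genes, 1.63 for mitotic genes, −1.16 for Aux/IAA genes, −0.92 for xylem, −1.29 for phloem and 0.65 for the stomatal lineage. For the quadruple against the double mutant there were 515 genes, with medians of 0.60 for GRF and GIF genes, 0.86 for mitotic genes, −0.94 for Aux/IAA genes, −1.14 for SAUR61 to SAUR68, −0.43 for xylem and −0.60 for phloem. In the double mutant margin library 3, 16.0% of reads aligned to several places, a share far above that of other libraries.

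For the interaction of the quadruple mutant with Col-0, depth, composition and a less clean cut of margin and center were weighed. After thinning to the smallest library 2403 genes were called, 2236 of the 3047 among them, which speaks against depth as the whole cause. Scaling without the 100 most abundant genes and the light harvesting list gave a mitotic median of 1.60 against 1.63. Group mean factors (0.90 to 1.11) differed too little to test composition. A less clean cut would shrink differences, whereas 42.9% of the genes called in both genotypes went in opposite directions. An effect of genotype stays open and untested, since staggered planting may confound it with plant age.

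In both mutants clock genes were shifted against Col-0, as a harvest at a later clock time would also give. In that case evening genes should be higher and morning genes lower, and of 15 clock members in the double mutant 0 of 14 called in the margin and 0 of 8 in the center went against that direction. In the quadruple mutant 0 of 11 and 2 of 9 did, LHY and RVE8. PRR7, the other gene of the clock list, was left out of these counts. In the quadruple mutant PRR7 was called lower in the margin and higher in the center than in Col-0. Whichever phase PRR7 has, it went against a later harvest in the margin or in the center. The labels give Zeitgeber time 6 for all libraries, but the values do not decide between a later harvest and an effect of the TCP genes on the clock, since the order of harvest is not stated.

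Iron deficiency genes, a list chosen after values were seen, were lower in the quadruple mutant margin, 15 of 18 with a median of −1.67. Without the Col-0 margin library 1 there were 17 of 19 lower, so that library alone did not set the difference. Iron supply of whole plants stays open. 11 of 18 members had an interaction, 10 lower and 1 higher (7 and 1 of 15 without FRO3, FRO7 and OPT3, named for one). In Col-0 12 were higher and 1 lower in the margin, so supply need not act alike on both pieces. In the center 7 were lower and 1 higher (median −0.492, p = 0.00202, p = 0.0873 with an estimated correlation). Fewer phloem cells in the margin could lower these genes, and the median of the list minus that of the phloem list (−1.68) was 0.0123 with a median absolute deviation of 2.33, which leaves that open. The list first chosen held 14 genes, 13 tested, with a median of −2.14 and a difference of −0.46. The 9 other genes and the spread rule were added after values were seen.

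The libraries were also split in other ways into groups of the same size, to see how many calls a wrong grouping gives. The true split gave the most calls in all 12 comparisons, 1 of 10 splits each, and 10 splits are too few for a share under 0.05. For margin against center the true count and the highest of the other splits were 2030 and 40 in Col-0, 1334 and 1 in the double mutant and 4552 and 0 in the quadruple mutant, and the other 3 splits that part as many leaf pools gave 0. In the margin they were 2513 and 1 for the double mutant and 7796 and 0 for the quadruple mutant against Col-0, and 4585 and 0 between the mutants. In the center they were 1093 and 0, 5520 and 0, and 1409 and 1. For the interactions, where whole leaf pools were exchanged, they were 78 and 0, 3047 and 0, and 515 and 0.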

How the results depend on the processing

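No call of a named gene was reversed in a refit, nor a list call in the 4 used. Over 13035 refits of named genes 842 calls were lost and 47 gained. Of 153 list calls in 360 tests 58 passed with an estimated correlation, which is stricter by construction. Among list tests the block lost 7 calls and gained 14, no filter lost 6 and gained 12, and DESeq2 size factors gained 1. With the leaf pool as a block the counts were 3836 for margin against center in Col-0, 3041 in the double and 6441 in the quadruple mutant, and 1347, 4996 and 2009 for the interactions of double with Col-0, quadruple with Col-0 and quadruple with double. The repetition number as a block changed the genotype comparisons little (2481, 7793 and 4611 in the margin, 1068, 5520 and 1380 in the center, in the order double against Col-0, quadruple against Col-0, quadruple against double). With only the libraries compared in the model, and so fewer samples, the counts were 764 for margin against center in the double mutant, 674 for double against Col-0 and 750 for quadruple against double in the center, and 39 for the interaction of the double mutant. That interaction gave 131 genes with DESeq2 and 175 without a filter, and the cause was not tested.

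Without single libraries, and so with fewer samples, counts ranged from 1377 to 1673 for margin against center in Col-0, 842 to 1147 in the double and 3305 to 3916 in the quadruple mutant. In the margin they were 1519 to 2361 for double against Col-0, 6884 to 7160 for quadruple against Col-0 and 3636 to 4016 for quadruple against double. In the center they were 462 to 1106, 4171 to 4888 and 841 to 1038, in the same order. For the interactions they were 17 to 208 for double with Col-0, 2254 to 2918 for quadruple with Col-0 and 269 to 658 for quadruple with double, and why single libraries moved the first and last so far was not tested. The slope of the double mutant on Col-0 went from 0.693 to 0.740 for genes selected at 2-fold, and its median ratio from 0.429 to 0.797.

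Added after the data were seen, the fit without the 2 libraries rich in reads aligned to several places and the fit on thinned counts moved no count by over 1.5 times. At 5.93 M reads in the smallest library, low counts limit TCP3 and other genes under a few CPM.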

Other observations

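The gene sets in this part were chosen after their values were seen, so they are no independent evidence, and their p values are not adjusted over sets. Genes of the iron deficiency response were higher in the Col-0 margin than in the center, 12 of 18 higher and 1 lower (camera p = 2.51e-07, p = 0.00914 with an estimated correlation, p = 1.31e-09 with the leaf pool as a block). They were lower in the double mutant margin than in that of Col-0, with 13 of 18 called (p = 6.5e-20, p = 0.000242 with an estimated correlation), and in the quadruple mutant margin, with 15 of 18 called (p = 7.4e-12, p = 0.00211 with an estimated correlation). The 4 ferritin genes, for iron storage, were all higher in the quadruple mutant margin than in its center, with a median log2 fold change of 1.06 (p = 0.000114, p = 0.0164 with an estimated correlation, p = 9.33e-09 with the leaf pool as a block), but against the Col-0 margin they did not pass (p = 0.155), nor did their interaction with an estimated correlation (p = 0.0525).

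Of genes known to rise in sugar starvation, 13 of 21 were higher and 0 lower in the quadruple mutant center than in that of Col-0, with a median of 0.82 (p = 7.05e-06, p = 0.101 with an estimated correlation). In the double mutant center 6 of 21 were higher, with a median of 0.56 (p = 9.8e-09, p = 0.0406 with an estimated correlation). In the margin the list did not pass in the quadruple mutant (p = 0.234), nor in the double mutant with an estimated correlation (p = 0.399). DYL1, a dormancy-associated gene among them, was at 9.29 ± 1.54 CPM (SD, n = 3) in the Col-0 center and 43.0 ± 13.7 in the quadruple mutant center. Of 168 groups of genes that share a symbol prefix, not always gene families, with at least 8 members tested, scanned in 12 comparisons, 167 results passed camera and 13 with an estimated correlation. One was the prefix COR, higher in the double mutant margin than in that of Col-0 with 6 of 8 members (adjusted p = 0.00784 with an estimated correlation). With that correlation adjusted p was 0.27 in the quadruple mutant margin (6 higher, 2 lower). In the centers (6 and 0 each) it was 0.000451 (double) and 0.00962 (quadruple).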
